A study of Drosophila melanogaster with 16 samples.

How the data were processed

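RNA-seq compared eye discs of mutants labelled Ez731, Su(z)12, PH505 (ph505) and Psc-Su(z)2 1.b8 (Psc-Su(z)2) with FRT controls, FRT2A for the first 2, FRT19A for ph505 and FRT42D for Psc-Su(z)2. ChIP-seq covered PC, PH, K27me3 and input in eye and wing discs, and K27ac in eye discs. Per the labels, RNA libraries started from 1 microgram of total RNA with 15 cycles of PCR and 50 cycles of single-read sequencing, and chromatin was fixed for 15 min in 1.8% formaldehyde. Per the labels, each sample stands for replicates 1 and 2 together, so every group was 1 sample. PCR without molecular identifiers means that reads are not independent molecules.

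Per the submitters' processing notes, the RNA-seq tools were TopHat2 2.0.8b, Bowtie2 2.1.0.0 and edgeR 2.6.2 with the BDGP5 build, and the ChIP-seq tools CASAVA 1.8.2 and SICER. How the replicates entered the authors' edgeR test, and the thresholds and build of the region lists, are not given in the sources used here. The log2 fold (logFC) and log2 CPM (logCPM) values are the authors' own, per the file headers. The p-value and the false discovery rate are likewise the authors', per the file headers, and the deposited tables list only genes with a false discovery rate under 5%. The region lists hold chromosome, start and end, as deposited, with no score. No other column was used. Since only called genes are listed, a gene missing from a table was not read as unchanged, no count model was fitted, and p-values measure the spread within the authors' own test, which may be technical.

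The number of genes tested was recovered as false discovery rate times rank over p, its most common value per table. Gene symbols came from a table of Drosophila gene identifiers, which gave no symbol for 43, 72, 136 and 289 identifiers of the 4 tables. The gene annotation used for neighbours was of Release 6 (ISO1), another build than the RNA-seq one, so only the order of its genes along each chromosome was used, for the test of neighbours, and binding at called genes was not run.

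The following choices were made before the data were examined. A total of 18 pathway lists and 8 lists of markers of other tissues were fixed. The direction of each list with at least 3 called members was tested with a two-sided Fisher exact test of higher against lower calls, members against all other called genes of the table, with Benjamini-Hochberg adjustment over 88 tests. Enrichment of lists among calls and overlaps of calls used the 6774 genes called in any table as universe (two-sided Fisher exact tests, 12 overlaps adjusted together). Same-direction shares had exact binomial tests, and correlations 100000 permutations. P-values of list members that were not called were not analysed here, so no count adjusted over the list alone is given. Named genes were the targeted genes, the 10 highest and 10 lowest log2 folds among calls at or above the median log2 CPM of the table (names with only a CG or CR number left out), called Hox and JAK-STAT members, up to 4 members of each other list that passed, and for shared sets the 10 genes with the largest smallest fold. Long sets are named in part, and some further list members are named for a contrast. Named regions came from the 5 widest per list and the 5 widest seen in 1 tissue alone.

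Regions on X, 2L, 2R, 3L, 3R and 4 with a width above 0 were kept, which left out at most 10 regions of a list. An overlap needed 1 bp. It was compared with 1000 circular shifts within each arm, whose length was taken as the largest region end in any list (one-sided permutation p, adjusted over 24 pairs). Shares have exact Clopper-Pearson 95% intervals, which cover counting error only, and eye and wing shares in K27me3 domains were compared by two-sided Fisher exact tests. Read depth of the libraries is unknown.

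Alternatives for gene results were a 1% false discovery rate, a change of at least 2-fold, expression at or above the table median, and other universes. For regions they were overlap of at least 50% of the region, width at or above the list median, 1 kb around the centre, and a 1 kb distance. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Tested on simulated data, the direction test found 100% of 200 planted lists of 10 genes in each of the 4 tables and called 7%, 1.5%, 1.5% and 2% of random lists at an unadjusted 0.05. All planted lists had the same split of higher and lower genes, so this share repeats a single calculation per table. It gives no power after adjustment: germ-line markers in Psc-Su(z)2, with 9 of 10 higher, did not pass (exact adjusted p = 0.0734). The shift test found 100% of 100 sets of 1000 regions with planted overlap and called 6% of random sets, against the 7290 eye K27ac regions.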

Results

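The series asked how Polycomb group proteins act during Drosophila development, with RNA-seq of mutant eye discs and ChIP-seq of eye and wing discs, all from L3 larvae. Imaginal discs are the larval epithelia that form adult structures, here the eye with its head parts and the wing. Polycomb group proteins repress developmental genes in 2 complexes. PRC2, which holds E(z) and Su(z)12, methylates histone H3 at lysine 27 (K27me3), and PRC1 holds Polycomb (PC), Polyhomeotic (PH) and Psc or Su(z)2. The 16 samples were 7 RNA-seq groups (4 mutants, labelled Ez731, Su(z)12, PH505, here ph505, and Psc-Su(z)2 1.b8, here Psc-Su(z)2, and 3 controls that carry only the FRT recombination site) and 9 ChIP-seq groups (5 from the eye disc, 4 from the wing disc, each tissue with its input). Each group was 1 sample that stands for 2 replicates per its label, with no values per replicate, so no spread between replicates could be given for any value. The authors' deposited tables list, per mutant, the genes called at a 5% false discovery rate with log2 fold, log2 CPM and p-values. Total reads per library are not given in the sources used here, so depth is unknown.

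The number of called genes differed widely among the 4 mutants. The authors' deposited table for Ez731 held 309 genes higher and 573 lower than in the FRT2A control, and that for Su(z)12 held 525 higher and 778 lower against the same control. The table labelled ph505 held 1064 higher and 1285 lower against FRT19A, and that for Psc-Su(z)2 held 3154 higher and 3016 lower against FRT42D. These were 9.87%, 14.6%, 26.7% and 69.4% of the 8934, 8907, 8804 and 8886 genes behind the authors' adjustment. Changes of at least 2-fold made up 52.3%, 51.3%, 34.8% and 40.2% of the calls. Depth is unknown and each arm is 1 sample that stands for 2 replicates, so these counts were not tested against each other.

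**Figure D1:**
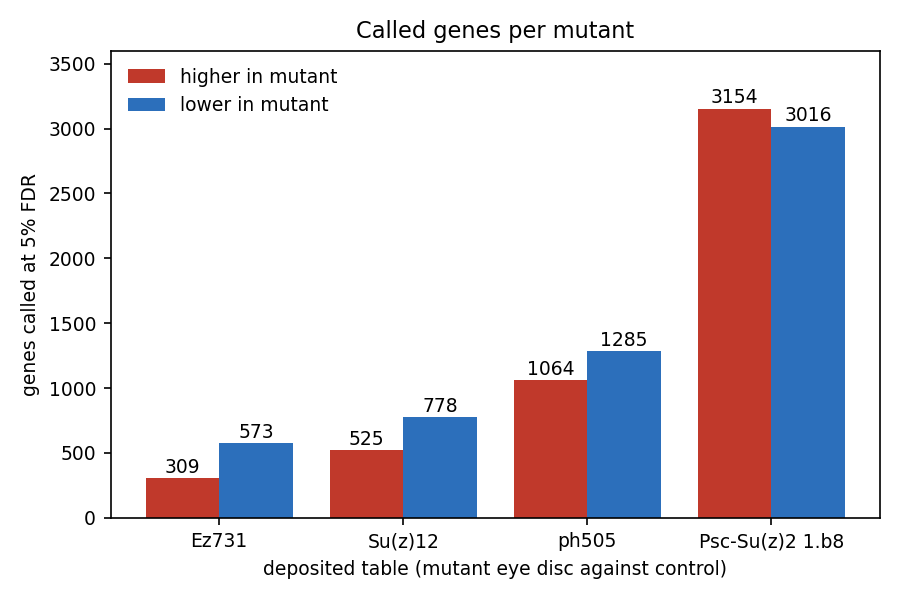
Number of genes called by the authors at a 5% false discovery rate (y axis) in each deposited table (x axis), with genes higher in the mutant in red and lower in blue. Calls ran from 309 higher and 573 lower genes in Ez731 to 3154 higher and 3016 lower in Psc-Su(z)2; there is 1 table per mutant and no error bar.

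The targeted genes were looked up first. In the authors' deposited tables E(z) (FBgn0000629) had a log2 fold of −0.99 in Ez731 (edgeR adjusted p = 8.29e-12), and Psc (FBgn0005624) of −3.94 in Psc-Su(z)2 (edgeR adjusted p = 9.33e-242). The tables do not state which arm is the numerator, and folds were read as mutant over control because of these 2 values. Su(z)12 is not listed in the Su(z)12 table, nor Su(z)2 in the Psc-Su(z)2 table. In the authors' deposited table labelled ph505 both ph genes were higher, ph-p (FBgn0004861) by 0.78 and ph-d (FBgn0004860) by 0.90, so transcript level does not bear out that label. Whether this allele lowers ph transcript is not given in the sources used here, so the ph values do not contradict the label either. Some other values of that table ran as in the other mutants, with Abd-B at 7.09, cad at 7.19 and pb at 6.45, 6 of 7 called Hox genes higher, and 87.8% of 1977 calls shared with Psc-Su(z)2 in the same direction. For these genes and shared calls the values argue against a turned direction, in which Abd-B, cad and pb would be higher in the control. The ph genes cannot decide the direction, so every direction from that table is given for the table so labelled. An alternative with its direction turned was added after these values were seen.

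In both PRC2 mutants the posterior Hox genes rose most among the named genes at or above the median log2 CPM of the table, together with germ-line genes. All highest and lowest genes of each mutant below are of that set, and other genes of a table can lie beyond them. Log2 folds in the authors' deposited Ez731 and Su(z)12 tables were 7.65 and 8.21 for Abd-B (FBgn0000015) and 6.26 and 6.70 for abd-A (FBgn0000014), which specify the abdomen. They were 4.14 and 4.20 for krimp and 1.72 and 2.11 for SoYb, both in the germ-line piRNA pathway, 2.84 and 2.31 for the Hox gene Scr, and 1.58 and 1.73 for the signalling gene Wnt4. The Ez731 table also gave 5.89 for Kots, 2.32 for mth, 1.54 for the nuclear receptor gene Hr4 and 1.43 for Blimp-1. The Su(z)12 table gave 2.43 for mth, 2.33 for mthl8, 1.79 for dsx, the sex determination gene, and 1.62 for del. The lowest fold in both deposited tables was that of Tektin-C (−6.06 and −8.54), and Dscam4 was also low (−3.62 and −3.91). Larval serum protein genes of the fat body were also low, with Lsp1alpha at −3.88 and −3.07, Lsp1beta at −3.22 and −2.96 and Lsp2 at −2.89 and −3.27. The remaining lowest genes of the set were Lsp1gamma (−3.24), PPO2 (−2.07), fon (−2.81 and −2.77), Fbp2 (−1.99 and −2.55), Fbp1 (−1.99 and −3.01), Obp99b (−2.47, Su(z)12) and twit (−2.42, Su(z)12).

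In the table labelled ph505 the highest named gene at or above the median expression was cad (FBgn0000251), a homeobox gene of the posterior body, at a deposited log2 fold of 7.19. The carbonic anhydrase gene CAH2 followed at 4.38, then osy at 3.53, Aldh at 3.02, Pepck1 at 2.84 and SP1173 at 2.77. The transcription factor genes chinmo and zfh1 stood at 2.46 and 2.09, Wnt4 at 2.45 and yuri at 2.19. The lowest of the same set in the authors' deposited table were the fat body genes Fbp1 (−4.21) and Lsp2 (−3.26), then Spn43Aa (−2.50), Cpr49Ac (−2.43), the ecdysone-inducible ImpE2 (−2.34), St2 (−1.96), regucalcin (−1.88), LManII (−1.85), SP1029 (−1.80) and Sb (−1.79).

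In Psc-Su(z)2 discs posterior homeobox genes and a JAK-STAT ligand gene were among the highest named genes at or above the median expression. In the authors' deposited table Abd-B stood at 8.61, Mur89F at 7.86, the Hox gene pb at 7.46, cad at 7.23 and upd3, which encodes a JAK-STAT ligand, at 7.20. Esp (6.48), bgm (6.0), yellow-b (5.77), the transcription factor gene Ets21C (5.57) and CAH2 (5.13) completed the 10 highest of that set. Its lowest in the deposited table were ImpE2 (−9.27), Spn43Aa (−8.53), the EGFR pathway protease gene ru (−7.65) and phtm (−6.89), an ecdysone synthesis gene. ImpE3 (−6.89), the photoreceptor receptor gene sev (−6.87), SP2353 (−6.60), twit (−6.57), superdeath (−6.37) and the Notch target E(spl)mdelta-HLH (−6.27) followed.

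Hox cluster genes rose in both PRC2 mutants, with 6 of 6 called members higher in Ez731 (exact adjusted p = 0.00927) and in Su(z)12 (exact adjusted p = 0.0185). Besides Abd-B, abd-A and Scr, deposited log2 folds in Ez731 and Su(z)12 were 4.91 and 2.89 for pb, 2.19 and 1.49 for Antp, and 5.01 and 3.67 for Ubx. In the table labelled ph505, 6 of 7 were higher (Abd-B 7.09, pb 6.45, Antp 3.46, abd-A 3.45, Ubx 2.91, Scr 2.83; lab −1.01), and the test was not passed (exact adjusted p = 0.128). In Psc-Su(z)2, 6 of 7 were higher (abd-A 6.83, Antp 2.87, Scr 1.86, Dfd 0.57; lab −2.39), again without passing (exact adjusted p = 0.225). Each list was tested by a two-sided Fisher exact test of higher against lower calls, members against all other called genes of the table, with adjustment over 88 tests. With calls at or above the median expression of their table, the exact adjusted p was 0.13 in Ez731 and 0.179 in Su(z)12. In each, 3 members were left, all higher, the most extreme split that 3 members can give.

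Genes of eye development fell in all 4 tables, and Notch pathway genes passed the test in 3. Of the retinal determination and photoreceptor list, 0 of 18 called members were higher in Ez731 (exact adjusted p = 0.00533), 0 of 23 in Su(z)12 (0.000311), 1 of 22 in ph505 (0.000882) and 1 of 26 in Psc-Su(z)2 (1.09e-05). Deposited log2 folds in the order Ez731, Su(z)12, ph505 and Psc-Su(z)2 were −1.57, −2.24, −1.03 and −5.65 for ato, the proneural gene of the photoreceptors. They were −1.43, −2.21, −1.03 and −6.21 for ro and −1.24, −2.17, −1.36 and −5.30 for sens, and the member that was higher in ph505 (0.52) and Psc-Su(z)2 (0.40) was Optix. Median folds of the list were −1.11, −1.52, −0.96 and −2.81. Notch pathway genes, mostly E(spl) and Bearded family targets, had 1 of 14 members higher in Su(z)12 (exact adjusted p = 0.0418), 0 of 16 in ph505 (0.00216) and 0 of 22 in Psc-Su(z)2 (1.39e-07 before and 1.09e-05 after adjustment). In Ez731 it was 1 of 11 (exact adjusted p = 0.204), with a median fold of −1.07, and no pair of tables as labelled differed in the direction of this list (Fisher exact adjusted p = 1). With the direction of the ph505 table turned, ph505 differed from Ez731, Su(z)12 and Psc-Su(z)2 (Fisher exact adjusted p = 2.14e-05, 2.69e-06 and 1.72e-09). The deposited folds of E(spl)m5-HLH were −1.52, −2.51, −0.73 and −4.96, and those of E(spl)m4-BFM −1.44, −2.22, −1.12 and −5.27. At 2-fold or more, the retinal and Notch lists no longer passed in ph505 (exact adjusted p = 0.091 and 0.163), nor Notch in Su(z)12 (0.126), which was also lost at a 1% false discovery rate (0.0769) and among well-expressed calls (0.0713).

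JAK-STAT pathway genes rose in the table labelled ph505, where 8 of 8 called members were higher (exact adjusted p = 0.00927). Deposited log2 folds there were 3.86 for upd3, 2.46 for chinmo, 2.09 for zfh1, 1.88 for upd2, 1.27 for upd1, 0.59 for Socs36E, 0.46 for Stat92E and 0.28 for dome, so ligands and targets were included. Among the authors' deposited Psc-Su(z)2 calls, 8 of 10 were higher (upd3 7.20, upd2 6.16, chinmo 4.57, zfh1 3.63, upd1 3.23, Socs36E 2.31, dome 1.01, Stat92E 0.43) and hop (−0.22) and Socs16D (−0.54) lower. That list did not pass there (exact adjusted p = 0.204). In Ez731 the called members were upd2 (1.62), upd1 (0.94) and et (−1.74, exact adjusted p = 0.414), and in Su(z)12 upd3 (1.93) and chinmo (0.61), too few for a test. With well-expressed calls alone the ph505 list did not pass (exact adjusted p = 0.158), with 5 members left, all higher.

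Several groups passed the test in some tables only, or in opposite directions in different tables. In the table labelled ph505, 9 of 9 called cell cycle genes rose (exact adjusted p = 0.00533; twe 0.84, dup 0.83, RnrL 0.75, PCNA 0.62), while 4 of 17 were higher in Psc-Su(z)2, which did not pass (exact adjusted p = 0.0902), nor did 0 of 3 in Su(z)12 (0.414; stg −0.87, dap −0.59, E2f1 −0.37). Polycomb group genes rose in ph505 with 8 of 8 higher (exact adjusted p = 0.00927; Psc 0.96, ph-d 0.90, esc 0.85, ph-p 0.78) and fell in Psc-Su(z)2 with 1 of 14 higher (0.00533; Psc −3.94, jing −1.14, ph-d −0.53, the higher one esc 0.60). Median log2 folds of that list were small, 0.59 in ph505 and −0.35 in Psc-Su(z)2, where Psc is a mutated gene. EGFR and FGF pathway genes fell in ph505, with 0 of 12 higher (exact adjusted p = 0.00533; ru −1.54, pyr −1.05), and did not pass in Ez731 (2 of 7 higher, 1), Su(z)12 (1 of 8, 0.26) or Psc-Su(z)2 (6 of 15, 0.603). Its direction in ph505 as labelled did not differ from that in these 3 tables (Fisher exact adjusted p = 0.586, 1 and 0.209), so passing in ph505 alone is not a difference between tables. With the direction of the ph505 table turned it differed from all 3 (Fisher exact adjusted p = 0.00989, 0.00108 and 0.00675). Ecdysone response genes rose in Ez731 (7 of 8, exact adjusted p = 0.0161; Hr4 1.54, Ldh 1.11) and fell in Psc-Su(z)2 (2 of 15 higher, 0.0161; ImpE2 −9.27, Hr3 −5.69), the exceptions there being Ldh (4.04) and ftz-f1 (1.64). In Su(z)12 and ph505 3 of 4 and 3 of 13 were higher (exact adjusted p = 0.446 and 0.268). Ldh is a glycolytic enzyme gene. Developmental transcription factor genes known as Polycomb targets rose in Ez731 (17 of 24, exact adjusted p = 0.00434; cad 5.02, croc 2.82) and fell in Psc-Su(z)2 (16 of 51 higher, 0.02; danr −5.32, B-H1 −5.17, against cad 7.23 and eve 6.89). In Su(z)12 and ph505 that list had 18 of 32 and 18 of 35 higher (exact adjusted p = 0.152 and 0.652). At 2-fold or more the Psc-Su(z)2 calls were lost for the ecdysone list (exact adjusted p = 0.207) and the transcription factor list (0.41). At that fold the cell cycle and Polycomb group lists kept no member in ph505, the EGFR and FGF list kept ru and pyr, and the Polycomb group list in Psc-Su(z)2 kept jing and the mutated Psc, too few to test. At or above the median expression the Psc-Su(z)2 calls of the ecdysone and transcription factor lists were lost too (exact adjusted p = 0.0713 and 0.111). So were the ph505 calls of cell cycle (exact adjusted p = 0.0646), Polycomb group (0.0713; 0.0545 at a 1% false discovery rate) and EGFR and FGF genes (0.0713) and the Ez731 call of transcription factor genes (0.0713).

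Germ-line genes rose in both PRC2 mutants, with 8 of 8 called members higher in Ez731 (exact adjusted p = 0.00314) and in Su(z)12 (0.00533). The authors' deposited log2 folds in Ez731 and Su(z)12 were 6.24 and 4.23 for bam, 2.96 and 2.15 for qin, and 1.45 and 1.72 for piwi. In ph505, 3 of 3 were higher and in Psc-Su(z)2 9 of 10 (exact adjusted p = 0.194 and 0.0734), where krimp was at −1.87 and mael at 5.07. Both PRC2 calls were lost among calls at or above the median expression (exact adjusted p = 0.13 and 0.179). There 3 members were left in each table, all higher, which is the most extreme split that 3 members can give.

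Markers of other tissues that can be dissected along with a disc were called in every table. In Ez731, Su(z)12 and ph505, fat body markers had 0 of 7, 0 of 7 and 0 of 8 called members higher, with deposited median log2 folds of −2.88, −2.96 and −2.99, a call in ph505 (exact adjusted p = 0.202, 0.12 and 0.0371). Muscle markers had 0 of 9, 0 of 10 and 0 of 13 higher (exact adjusted p = 0.0976, 0.0294 and 0.00456; in ph505 Act87E −2.17, up −2.12, TpnC73F −2.10 and Tm2 −2.05). Hemocyte markers, of blood cells, had 1 of 10, 1 of 10 and 1 of 9 higher (exact adjusted p = 0.286, 0.135 and 0.12), the exception in each being Ppn. In Psc-Su(z)2 hemocyte markers rose, 11 of 11 (exact adjusted p = 0.00625; gcm2 2.59, Ppn 2.34, Sr-CI 2.24, srp 2.13), while 4 of 14 muscle markers and 2 of 3 fat body markers were higher (exact adjusted p = 0.204 and 1). The ph505 fat body call and the Su(z)12 muscle call were lost at a 1% false discovery rate (exact adjusted p = 0.112 and 0.088), and the Psc-Su(z)2 hemocyte call among well-expressed genes (0.118). At 2-fold or more the fat body call (exact adjusted p = 0.163) and the muscle calls of Su(z)12 (0.163) and ph505 (0.091) were lost, and the Su(z)12 muscle call also among well-expressed genes (0.077). Among these, fat body and muscle markers kept 2 and 1 members in ph505, too few to test.

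**Figure D2:**
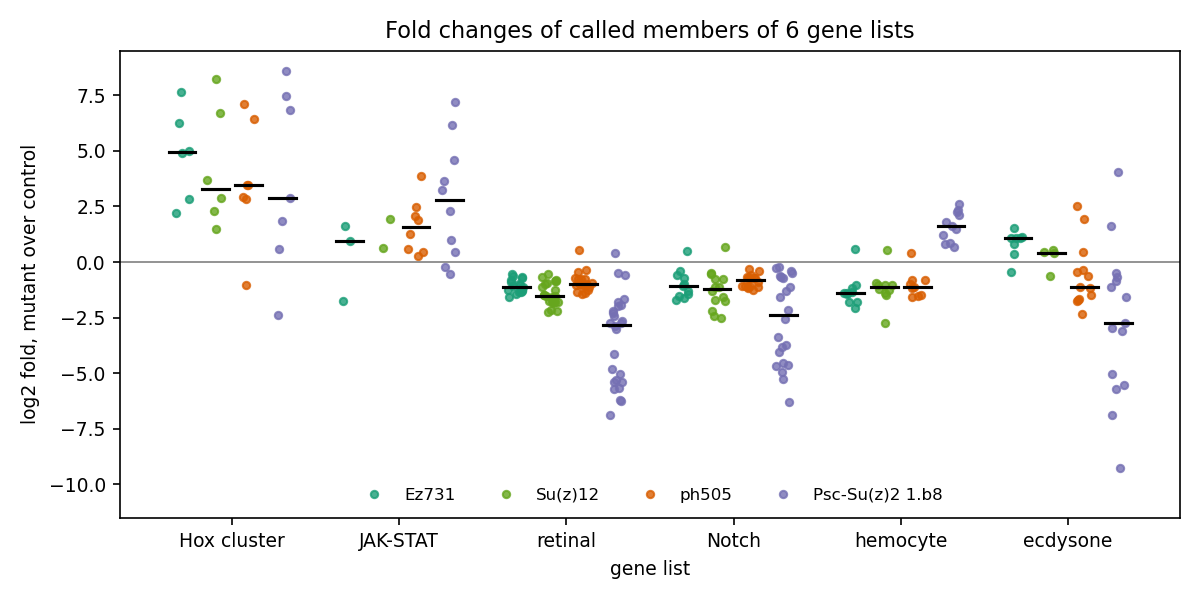
Log2 fold, mutant over control, from the authors' deposited tables (y axis) of each called member of 6 gene lists (x axis). A point is a gene, colours are the 4 tables, and black bars are medians of lists with at least 3 called members. The retinal medians were −1.11, −1.52, −0.96 and −2.81, and all 11 called hemocyte markers lay above 0 in Psc-Su(z)2.

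The same genes were often called in pairs of mutants. Ez731 and Su(z)12 shared 209 higher and 413 lower genes (odds ratios 40.7 and 41.3 among the 6774 genes called in any table; exact adjusted p = 1.23e-170 and 1.12e-299), and 98.6% of their 631 shared calls had the same direction (exact 95% interval 97.3 to 99.4). The table labelled ph505 and Psc-Su(z)2 shared 767 higher and 969 lower genes (odds ratios 3.60 and 5.16; exact adjusted p = 1.06e-74 and 3.73e-137), with 87.8% of 1977 in the same direction, or 12.2% with the direction of the ph505 table turned. Across complexes the same-direction share was 72.0% of 478 for Ez731 and ph505 and 67.2% of 692 for Ez731 and Psc-Su(z)2. It was 81.6% of 729 for Su(z)12 and ph505 and 77.0% of 1061 for Su(z)12 and Psc-Su(z)2. All 6 shares lay above 50% (largest exact binomial adjusted p = 9.01e-20), but with the ph505 direction turned its shares with Ez731 and Su(z)12 were 28.0% and 18.4%. Odds ratios across complexes, higher then lower genes, were 1.64 and 4.67 for Ez731 with ph505 (exact adjusted p = 0.000671 and 2.01e-60), 2.67 and 7.53 for Su(z)12 with ph505 (5.21e-20 and 1.79e-133), and 1.28 and 3.29 for Su(z)12 with Psc-Su(z)2 (0.00721 and 2.75e-51). Genes lower in Ez731 and Psc-Su(z)2 overlapped with an odds ratio of 2.07 (exact adjusted p = 3.36e-16), which was lost at 2-fold or more (1.04, 0.763) and at or above the median expression (1.18, 0.241). For higher genes, the call of Su(z)12 with Psc-Su(z)2 was lost at a 1% false discovery rate (1.09, exact adjusted p = 0.419), at 2-fold (1.28, 0.117) and at or above the median expression (1.07, 0.577), where the ratio of Ez731 with ph505 was 0.811 (0.441). Genes higher in Ez731 and Psc-Su(z)2 overlapped less than chance within the called genes (116 genes, odds ratio 0.678, exact adjusted p = 0.00141). Genes called nowhere are missing from this background, which pushes odds ratios down. That last direction did not hold with the 8886 tested genes as background (odds ratio 1.10, exact adjusted p = 0.468), a background chosen after the values were seen. At 2-fold or more it did not pass (0.760, exact adjusted p = 0.175). Without the Psc-Su(z)2 table in the background, the higher genes of ph505 had odds ratios of 0.530 with Ez731 and 0.820 with Su(z)12, and with the tested genes as background 2.25 and 3.69 (exact adjusted p = 6.33e-08 and 5.65e-33).

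Fold changes of shared calls correlated across genes, which are not independent replicates and were selected as called, so that r is inflated. Pearson's r was 0.947 for Ez731 and Su(z)12 and 0.712 for ph505 and Psc-Su(z)2 (Spearman's rho 0.930 and 0.735), and for the other pairs r was 0.479, 0.314, 0.574 and 0.525. Every permutation p was 1e-05, the smallest that 100000 permutations can give, with the same value after adjustment over 6 pairs. Without the 2 genes farthest from the median fold of the first table, r was 0.944 and 0.713. Ez731 and Su(z)12 share their FRT2A control. In 100 simulations of unchanged groups against one control, r over all genes was 0.500, and at most 2 genes were called with 0 shared. These held independent noise with a matching test, so few calls were given in advance, and their r is not one of selected calls. The covariance of the folds was 2.76, against 0.044 from the sampling error of the shared control. Neither value covers a control that differs by more than sampling error, so neither shows its part to be small. Among the 6774 called genes, independent lists would share 23.95 higher and 65.8 lower genes. How much of the excess comes from the shared control, which is 1 sample, could not be split off.

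Genes changed in both PRC1 mutants were mostly not called in the same direction in a PRC2 mutant. Of the 767 genes higher in both PRC1 tables, 51 were higher in all 4 tables, 105 in 1 PRC2 table and 611 (79.7%) in neither. Of the 969 lower genes these numbers were 188, 193 and 588 (60.7%). Of the 6774 genes called in any table, only 309 and 525 were higher in Ez731 and Su(z)12, and 573 and 778 lower. Most called genes thus lie in neither PRC2 list of a direction. The share expected from these list lengths was not computed, so 79.7% and 60.7% do not show independence from PRC2. With the direction of the ph505 table turned, 132 genes were higher in both PRC1 tables, of which 6 were higher in all 4, 8 in 1 PRC2 table and 118 (89.4%) in neither, and of 109 lower genes 13, 11 and 85 (78.0%). The sets named below rest on the deposited direction. Another 108 genes were higher in both PRC2 tables and in no PRC1 table, and 82 were lower, or 74 and 117 with the direction of the ph505 table turned. A call in the opposite direction was not counted, so that ImpE2, lower in both PRC1 tables, was higher in Ez731 (deposited log2 fold 1.09) and Su(z)12 (0.43). A gene missing from a table is not shown to be unchanged there, and these sets depend on how many genes each table calls.

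Named genes higher in all 4 tables, ordered by their smallest fold, were led by Hox genes and other developmental regulators. In the order Ez731, Su(z)12, ph505 and Psc-Su(z)2, the authors' deposited log2 folds were 5.02, 7.02, 7.19 and 7.23 for cad and 4.50, 4.26, 6.28 and 5.80 for Ilp8, a relaxin-like peptide that delays metamorphosis. They were 4.62, 5.42, 3.21 and 4.66 for HGTX, 2.82, 3.59, 2.34 and 3.22 for croc, 2.15, 3.16, 4.69 and 4.91 for byn and 1.58, 2.23, 4.39 and 5.57 for Ets21C. Abd-B, abd-A, pb and Scr made up the rest of the 10 largest. Genes lower in all 4 included Fbp1, Cralbp, Mhc, P5CS, TpnC25D, sev, Lcp65Ad, sens, Prm and phyl. Median folds of the 51 higher genes were 1.09, 1.38, 1.65 and 2.34, and of the 188 lower genes −0.88, −1.24, −0.96 and −3.70.

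By the same order, named genes higher in both PRC1 tables and higher in no PRC2 table were led by eve, the pair-rule homeobox gene, with deposited log2 folds of 7.89 in ph505 and 6.89 in Psc-Su(z)2. Sox15 (5.62 and 5.89), CAH2, fd102C (4.25 and 4.94), Sox100B (3.73 and 6.71), unpg (5.46 and 3.42) and tin (5.41 and 3.18) followed, then Aldh, GstD2 and Rcd2. The lower ones were led by Spn43Aa, Cpr49Ac and ImpE2. In the authors' deposited Ez731 and Su(z)12 tables, genes higher in both and higher in no PRC1 table were led by Kots, HP1D3csd (4.87 and 4.61), bam, krimp, moon (3.44 and 4.76) and SPE (3.28 and 4.82). The lower ones were led by Gnmt (−3.87 and −3.56), TrpA1 (−3.45 and −3.50), Npc2g (−2.89 and −2.86), Tps1 (−3.15 and −2.85) and gcm (−2.66 and −2.87). Some genes of these PRC2 sets were called in the opposite direction in Psc-Su(z)2, among them gcm (2.53) and krimp (−1.87).

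Among genes higher in both PRC1 tables, 0 of 5 Hox genes, 0 of 3 wing disc markers, 1 of 7 JNK and wound genes and 5 of 12 developmental transcription factor genes lacked a PRC2 call in that direction, against about 80% of other genes (exact adjusted p = 0.00229, 0.0248, 0.00229 and 0.0144 over 18 tests). The 3 wing disc markers, vg, nub and tup, are also among the 12 transcription factor genes, so the results of these lists are not separate. Among genes lower in both, 2 of 21 retinal genes, 3 of 16 Notch pathway genes and 2 of 10 muscle markers lacked one (exact adjusted p = 2.31e-05, 0.00458 and 0.0386). All 9 ecdysone response genes lower in both lacked a PRC2 call in that direction, against 60.3% of other genes (exact adjusted p = 0.0363). With the direction of the ph505 table turned, none of these comparisons kept the 3 members that the test needs, so all of them were tested only in the direction as labelled.

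The K27me3 lists of both discs held domains of over 100 kb, but also narrow regions, with lower quartiles of 1301 bp in the eye and 1001 bp in the wing. The eye disc had 349 K27me3 domains with a median width of 7701 bp that covered 7.68% of the arms, 2027 PC regions (1193 bp, 2.51%), 3370 PH regions (1249 bp, 3.94%) and 7290 K27ac regions (2677 bp, 21.6%). K27ac, acetylated lysine 27 of histone H3, marks active chromatin. The wing disc had 583 K27me3 domains (2351 bp, 8.41%), 3716 PC regions (1684 bp, 6.94%) and 5062 PH regions (1551 bp, 7.67%). Coordinates are 1-based and from the deposited lists, and the build of the region lists is not given in the sources used here, so what is annotated there was not analysed here. The widest eye domains lay on 3R from 2649701 to 2891451 (242 kb) and from 12588001 to 12813951 (226 kb). The next lay on 2L from 21796001 to 21980451 and from 11318001 to 11495951, and on 3L from 12553501 to 12724451. In the wing disc both 3R domains were again the widest, 241 and 226 kb, followed by 3L from 12532501 to 12725451, 2L from 21796101 to 21980451 and X from 7408151 to 7568951. The widest PC regions were on 2L from 3532096 to 3544870 in the eye (12.8 kb) and on 3R from 3974070 to 4002355 in the wing (28.3 kb). The widest PH regions were on 3R from 6350342 to 6357721 in the eye (7.38 kb) and on 3L from 3244475 to 3256193 in the wing (11.7 kb). Counts were not tested, with 1 list per antibody and tissue and unknown depth.

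PC and PH regions overlapped far more than shifted regions in both discs. In the eye disc 81.8% of PC regions overlapped a PH region (exact 95% interval 80.1 to 83.5), against a mean of 7.38% over 1000 circular shifts, and 50.1% of PH regions overlapped PC (48.4 to 51.8; shifted 4.50%). In the wing disc these shares were 69.0% (67.5 to 70.5; shifted 15.2%) and 53.5% (52.1 to 54.9; shifted 11%). K27ac regions overlapped 59.8% of eye PC and 62.5% of eye PH regions (shifted 27% each), while 24.1% of K27me3 domains overlapped K27ac (19.7 to 28.9; shifted 49.3%, lowest 41.3%). With 1 kb around centres, which also narrows K27ac regions, the PC and PH shares were 33.2% and 36.4% (shifted 11.9% and 12%). Of the 24 ordered pairs tested within and between discs, all but the 2 of K27me3 with K27ac in the eye disc had more overlap than every shifted set (one-sided permutation p = 0.001, the smallest possible, adjusted p = 0.00109). That K27me3 and K27ac overlapped less than every shifted set had the same permutation p, in a test of less overlap chosen after the values were seen.

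Of the deposited lists, most PC and PH regions lay outside K27me3 domains in both discs. In the eye disc 774 of 2027 PC regions (38.2%, exact 95% interval 36.1 to 40.3) and 790 of 3370 PH regions (23.4%, 22.0 to 24.9) overlapped a domain. In the wing disc it was 1549 of 3716 PC regions (41.7%, 40.1 to 43.3) and 1103 of 5062 PH regions (21.8%, 20.7 to 22.9). Eye minus wing differences were −3.50 points for PC (Fisher exact adjusted p = 0.0157) and 1.65 points for PH (0.0787; 0.0167 at 50% overlap), and the shares of PH regions shared with PC were 40.7% and 34.1% (3.61e-05). These p-values compare regions of 1 list per disc, and the lists differ in length and have unknown depth, so they are no test of a difference between the discs. Neighbouring regions are not independent either, and among regions at or above the median width of their list 52.9% of eye and 46.3% of wing PC regions lay in domains, which turned the difference to 6.64 points (exact adjusted p = 0.00103). In a comparison chosen after the values were seen, 77.0% of eye PH regions outside domains overlapped K27ac (75.3 to 78.6) against 15.1% inside (12.6 to 17.8; Fisher exact p = 7.63e-221). For eye PC regions these shares were 87.1% (85.1 to 88.9) and 15.6% (13.1 to 18.4; Fisher exact p = 8.79e-240). With 1 kb around centres, which also narrows K27ac regions, they were 44.6% and 8.88% for PH, and 48.4% and 8.33% for PC. Both marks sit on the same lysine, and of all K27ac regions 2.99% overlapped a domain, against 8.58% shifted. Low K27ac overlap inside domains is thus not shown to be particular to PC or PH regions.

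**Figure D3:**
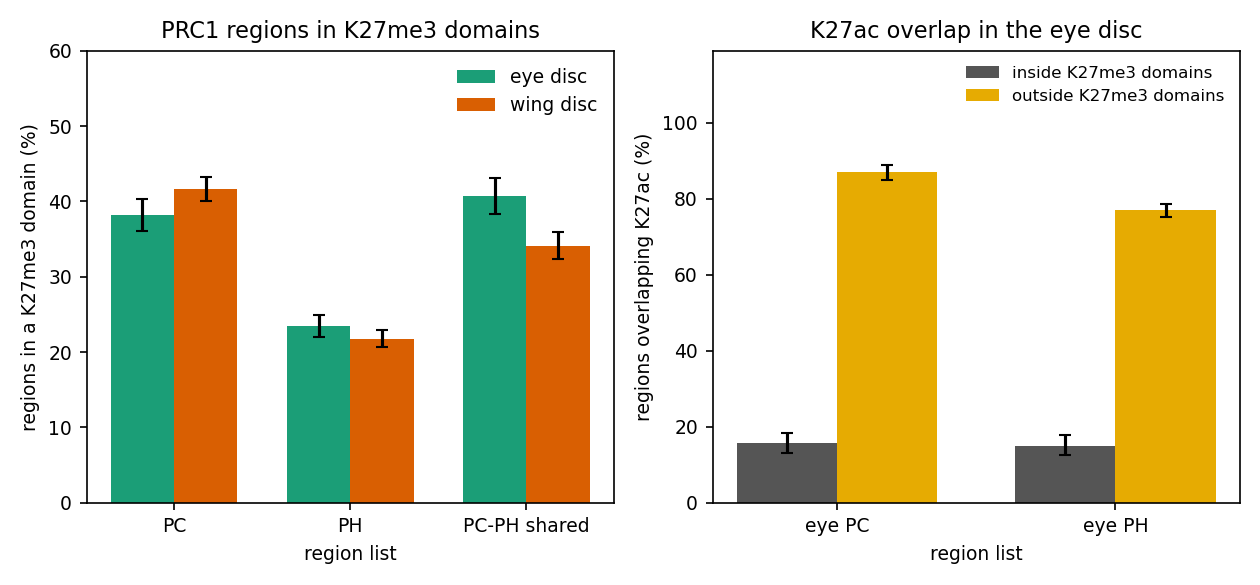
Left, percent of PC regions, PH regions and PH regions shared with PC that overlap a K27me3 domain by at least 1 bp in eye and wing disc. Right, percent of eye PC and PH regions that overlap a K27ac region, inside and outside K27me3 domains; bars are exact 95% intervals, which cover counting error alone. Of eye PH regions, 23.4% lay in a domain, and K27ac overlap was 15.1% inside and 77.0% outside.

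Eye regions were mostly found in the wing disc. Of eye PC, PH and K27me3 regions, 78.8% (77.0 to 80.6), 88.5% (87.4 to 89.6) and 77.9% (73.2 to 82.2) overlapped a wing region of the same antibody, against shifted means of 10.3%, 12.7% and 17.4%. Of wing regions, 37.4%, 53.7% and 45.8% overlapped an eye region (shifted 5.49%, 8.17% and 11.4%). The wing lists were longer, 3716, 5062 and 583 regions against 2027, 3370 and 349, which by itself lowers the share of wing regions that can be matched, and the 2 directions were not tested against each other. Regions seen in the eye disc alone numbered 429 for PC, 386 for PH and 77 for K27me3, and in the wing disc alone 2328, 2344 and 316. The widest K27me3 domains of the eye without a wing counterpart lay on 3R from 23005901 to 23063451 and on X from 264501 to 321451 (57.6 and 57.0 kb). Those of the wing without an eye counterpart lay on 2R from 19137801 to 19242451 (105 kb) and on 3R from 11351001 to 11426951 (76.0 kb). The widest PC region of the eye alone was on 2L from 497526 to 508597 (11.1 kb), and that of the wing alone on 3L from 658869 to 677702 (18.8 kb). The widest PH regions of 1 disc alone were on 3L from 19899629 to 19903863 in the eye and on 3R from 3993258 to 4002291 in the wing. Presence in 1 list and not the other is not a test of a difference in binding.

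**Figure D4:**
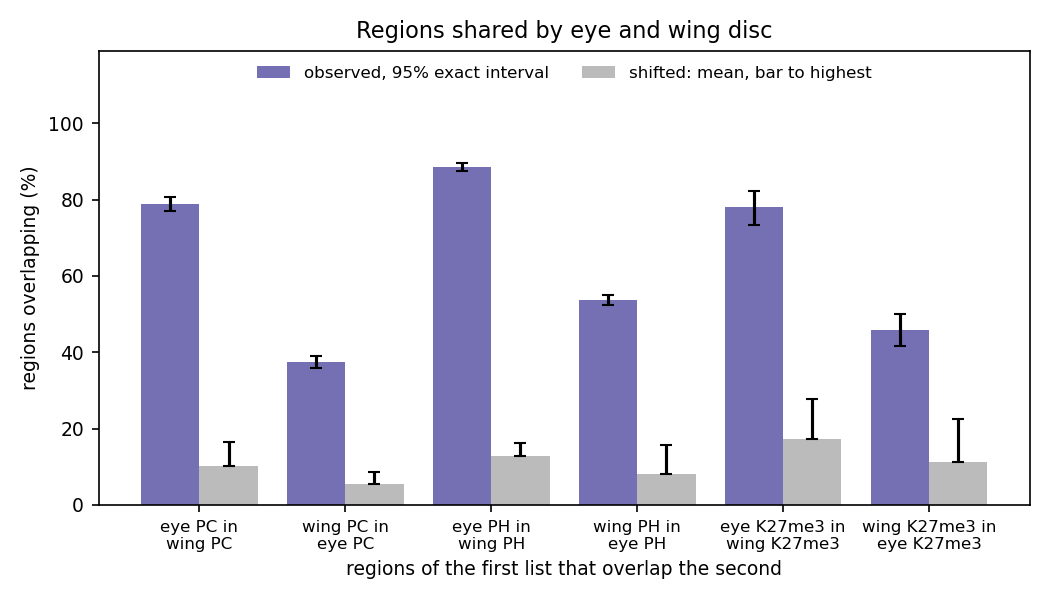
Percent of regions of the first list that overlap a region of the second by at least 1 bp (purple, with exact 95% intervals), beside the mean of 1000 circular shifts (grey, with a bar up to the highest). Eye regions were found in the wing disc for 78.8% of PC, 88.5% of PH and 77.9% of K27me3.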

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

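The comparisons of list directions between tables, the tests of explanations except that on further fat body genes, and the turned direction of the ph505 table were chosen after the values were seen. Each item below differed in direction between tables by a two-sided Fisher exact test of higher against lower called members, adjusted over 115 comparisons, and the tables had different controls. Many members are called in both tables of a pair, and the test ignores this pairing. Members of a list are not independent of each other either, and each arm is 1 sample. The p-values are thus no test of a difference between the mutants. Hemocyte markers were higher in Psc-Su(z)2 (11 of 11) and lower in Ez731 (9 of 10, exact adjusted p = 0.0013), Su(z)12 (9 of 10, 0.0013) and ph505 (8 of 9, 0.00205). Polycomb group genes were higher in ph505 (8 of 8) and lower in Psc-Su(z)2 (13 of 14, exact adjusted p = 0.0013). Cell cycle genes were higher in ph505 (9 of 9) and lower in Psc-Su(z)2 (13 of 17, exact adjusted p = 0.0105). Ecdysone response genes were higher in Ez731 (7 of 8) and lower in Psc-Su(z)2 (13 of 15, exact adjusted p = 0.02005). Developmental transcription factor genes known as Polycomb targets were higher in Ez731 (17 of 24) and lower in Psc-Su(z)2 (35 of 51, exact adjusted p = 0.0395). With the direction of the ph505 table turned, its 3 differences from Psc-Su(z)2 did not pass (exact adjusted p = 0.835 for hemocyte markers, 1 for Polycomb group genes and 0.571 for cell cycle genes). It then differed from Psc-Su(z)2 in the retinal, Notch, muscle, JAK-STAT, EGFR and FGF, and ecdysone lists (largest exact adjusted p = 0.00934). It also differed from both PRC2 tables in the hemocyte, fat body, muscle, germ line, Hox, retinal, Notch, and EGFR and FGF lists (largest exact adjusted p = 0.0268).

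Most called markers of fat body, hemocytes and muscle lay lower in Ez731, Su(z)12 and ph505, while hemocyte markers lay higher in Psc-Su(z)2. Of the lower lists, only fat body in ph505 and muscle in Su(z)12 and ph505 passed the direction test. Attached tissue is a candidate explanation. One common change in all attached tissue is argued against in Psc-Su(z)2, where 11 of 11 hemocyte and 4 of 14 muscle markers were higher (Fisher exact p = 0.000545). An excess of such tissue in the FRT2A control stays open for Ez731 and Su(z)12, which share it. In ph505, with another control, 8 of 8 fat body markers were lower (exact binomial p = 0.00781). This is part of the pattern itself and rests on the direction as labelled, which the ph genes do not bear out. Less fat body in the mutant libraries of these 3 tables stays open too. Of 10 further fat body genes, 8 of which had a name in the gene table, 100% of 5 calls were lower, or 4 of 5 with the direction of the ph505 table turned, and these came from Apoltp and Jabba alone. A minimum of 3 distinct genes, added only after this result was seen, left the test undecided. Jabba and Tsf1 were also lower in Psc-Su(z)2 (deposited log2 folds −1.84 and −2.47), and a change of the genes themselves in the mutants was not tested.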

How the results depend on the processing

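The alternatives were fixed before the data were examined, except the background of genes tested, PRC1 calls from Psc-Su(z)2 alone, the turned direction of the ph505 table, and the settings of the K27ac comparison inside and outside domains, whose odds ratio stayed below 1 and past the threshold in all 4 for eye PH and for eye PC. Of 461 values under alternatives, 338 kept their direction and side of the threshold (or stayed near the main value), among them 18 of 21 same-direction shares. Depth is unknown, so what it limits was not analysed here. Binding at called genes was not run, and no replicate could be left out. No paired analysis was possible because each group was 1 sample with no values per replicate. In the lists below tables stand in the order Ez731, Su(z)12, ph505, Psc-Su(z)2, and where no cause is given the cause was not tested. At 2-fold or more, higher genes numbered 154, 214, 272 and 996 and lower genes 307, 455, 545 and 1486. At or above median expression, which removes about 50% of genes by construction, they numbered 164, 282, 623 and 1723, and 277, 370, 552 and 1362. Genes higher in all 4 tables numbered 24 at 2-fold, 16 at median expression and 94 with Psc-Su(z)2 alone for PRC1. Higher genes with 1 PRC2 table numbered 68 at a 1% false discovery rate, 27 at 2-fold, 51 at median expression and 202 with Psc-Su(z)2 alone, and those without PRC2 calls 99, 401 and 2858 in the last 3 settings. For PRC2 without PRC1 they were 58 at 2-fold and 61 at median expression. At 2-fold, median expression and Psc-Su(z)2 alone, lower genes numbered 38, 77 and 284 in all 4 tables, 73, 67 and 324 with 1 PRC2 table, and 242, 281 and 2408 with none. Each setting of the list tests kept a subset of the same calls and folds. A list whose members all lay in 1 direction could therefore only keep it. List directions held in the 66 of 72 tests that could be run outside the turned ph505 table, and with fewer calls 26 of these 66 no longer passed. The other 6 kept fewer than 3 members, 4 at 2-fold (ph505 cell cycle, Polycomb group and EGFR and FGF genes, Psc-Su(z)2 Polycomb group genes) and 2 at median expression (ph505 fat body and muscle). At a 1% false discovery rate the tests that no longer passed were ph505 fat body (0% higher, exact adjusted p = 0.112), Su(z)12 muscle (0%, 0.088), ph505 Polycomb group genes (100%, 0.0545) and Su(z)12 Notch (7.14%, 0.0769). At 2-fold they were ph505 fat body (0%, exact adjusted p = 0.163), muscle in Su(z)12 and ph505 (0% each, 0.163 and 0.091), ph505 retinal genes (0%, 0.091) and Notch in Su(z)12 and ph505 (0% each, 0.126 and 0.163). In Psc-Su(z)2 they were developmental transcription factors (31.7%, exact adjusted p = 0.41) and ecdysone genes (16.7%, 0.207). At median expression they were Ez731 and Su(z)12 germ line and Hox genes (100% each, exact adjusted p = 0.13 and 0.179), Ez731 transcription factors (68.8%, 0.0713), and Su(z)12 muscle (0%, 0.077) and Notch (8.33%, 0.0713). In ph505 they were Polycomb group genes (100%, exact adjusted p = 0.0713), JAK-STAT (100%, 0.158), EGFR and FGF (0%, 0.0713) and cell cycle genes (100%, 0.0646). In Psc-Su(z)2 they were hemocyte markers (100%, exact adjusted p = 0.118), transcription factors (26.7%, 0.111) and ecdysone genes (18.2%, 0.0713). Fat body markers, called less often than other genes in Psc-Su(z)2 (odds ratio 0.0485), had an odds ratio of 1.09 with all named genes as universe. Overlap odds ratios of higher genes moved with the universe. For Ez731 and ph505 the ratio was 0.811 at median expression and 0.530 without the Psc-Su(z)2 table. For Ez731 and Psc-Su(z)2 it was 0.760 at 2-fold, 0.796 without the Ez731 table, 1.08 without the Psc-Su(z)2 table, 1.10 with the tested number and 4.10 with all named genes. Lower genes of that pair had 1.04 at 2-fold and 1.18 at median expression. For Su(z)12 and ph505 it was 0.820 without the Psc-Su(z)2 table. For Su(z)12 and Psc-Su(z)2 it was 1.09 at a 1% false discovery rate, 1.28 at 2-fold, 1.07 at median expression and 1.17 without the ph505 table. For region numbers the alternative named a score, which the lists lack, so width was used. Keeping regions at or above the median width, which removes about 50% by construction, left 175 eye K27me3, 1015 eye PC, 1685 eye PH, 3647 eye K27ac, 292 wing K27me3, 1861 wing PC and 2531 wing PH regions, and merging those closer than 1 kb left 3912 eye K27ac. With overlap of 50% of the domain, PH covered 1.43% of eye and 3.26% of wing K27me3 domains, no more than shifted regions. By width, shares in K27me3 domains were 52.9% of eye PC, 46.3% of wing PC, 48.2% of eye and 37.0% of wing PH regions shared with PC. With 1 kb around centres the last 2 were 37.8% and 26.4%. With a 1 kb distance they were 43.7% of wing PC, 25% of eye PH and 24.0% of wing PH, and with 50% overlap 20.1% of wing PH. The eye minus wing difference of PC turned to 6.64 points by width, and that of PH passed at 50% overlap (2.31 points, exact adjusted p = 0.0167) and with 1 kb around centres (2.12 points, 0.0221). With the direction of the ph505 table turned, list shares reversed by construction, to 100% higher for fat body, muscle, Notch and EGFR and FGF genes, 95.5% for retinal genes, and 0% for Polycomb group, JAK-STAT and cell cycle genes. Its same-direction shares became 28.0% with Ez731, 18.4% with Su(z)12 and 12.2% with Psc-Su(z)2. Odds ratios of its shared genes became 0.901 (higher) and 0.278 (lower) with Su(z)12, 0.0935 and 0.110 with Psc-Su(z)2, and 0.523 for lower genes with Ez731. Genes of both PRC1 tables then numbered, with 2, 1 and no PRC2 tables, 6, 8 and 118 higher and 13, 11 and 85 lower.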

Other observations

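All comparisons in this part were chosen after the values were seen, apart from the list tests. Further lists did not pass the direction test in any table. JNK pathway and wound genes had 3 of 6, 7 of 9, 7 of 12 and 12 of 15 called members higher in Ez731, Su(z)12, ph505 and Psc-Su(z)2 (exact adjusted p = 0.588, 0.104, 0.554 and 0.104). In the authors' deposited tables the matrix protease gene Mmp1 was higher in all 4 by 1.04, 1.55, 1.04 and 2.41 and Mmp2 lower by −0.88, −1.33, −0.81 and −4.50 on the log2 scale. BMP and activin pathway genes had 4 of 4, 5 of 6, 4 of 9 and 4 of 15 higher (exact adjusted p = 0.0524, 0.117, 1 and 0.152), Wnt genes 2 of 4, 2 of 4, 1 of 7 and 3 of 13 (0.742, 1, 0.24 and 0.128) and Hedgehog genes 0 of 3, 1 of 4, 2 of 4 and 2 of 9 (0.709, 0.765, 1 and 0.202). Wing disc markers had 3 of 3, 3 of 3, 4 of 5 and 4 of 5 higher (exact adjusted p = 0.117, 0.147, 0.287 and 0.533), among them vg, the wing selector gene, at 1.24, 2.15, 4.43 and 3.80 in the authors' deposited tables. Neuron markers had 0 of 3, 1 of 8, 2 of 7 and 2 of 9 higher (exact adjusted p = 0.709, 0.26, 0.623 and 0.202) and glia markers 1 of 4, 1 of 4, 2 of 4 and 4 of 8 (1, 0.765, 1 and 1).

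Apoptosis genes had 3 of 3 called members higher in Su(z)12 and 2 of 8 in Psc-Su(z)2 (exact adjusted p = 0.147 and 0.278). In ph505 and Psc-Su(z)2, tracheal markers had 1 of 3 and 3 of 6 higher (exact adjusted p = 1 and 1), Hippo pathway genes 2 of 5 and 6 of 12 (1 and 1), polarity and junction genes 2 of 3 and 4 of 12 (0.725 and 0.39), heterochronic genes 2 of 3 and 2 of 3 (0.725 and 1), and immune effector genes 2 of 3 and 5 of 6 (0.725 and 0.339). Among enrichment tests of lists in the called genes (104 tests), 18 of 26 retinal genes and 24 of 54 developmental transcription factor genes were called in Ez731, against about 13% of other genes (exact adjusted p = 2.88e-09 and 3.17e-07). Some markers of other tissues were enriched among the same calls, with 10 of 12 hemocyte, 7 of 9 fat body and 9 of 16 muscle markers called (exact adjusted p = 1.43e-06, 0.000183 and 0.000402). Neuron, tracheal and wing disc markers were not (exact adjusted p = 0.328, 0.719 and 0.0888). In Psc-Su(z)2 about 91% of the genes in this universe were called, so hardly any list could pass as enriched there. Hemocyte and muscle markers did not pass, with 11 of 12 and 14 of 16 called. Fat body markers were called less often than other genes (exact adjusted p = 0.000283). With all named genes as universe, hemocyte and muscle markers had odds ratios of 10.7 and 13.6 (exact adjusted p = 0.0001055 and 4.91e-06), and fat body markers of 1.09.

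Of eye PC and PH regions outside K27me3 domains, 87.1% and 77.0% overlapped a K27ac region by at least 1 bp. With 1 kb around centres, which also narrows K27ac regions, these shares were 48.4% and 44.6%. Unspecific signal at active chromatin is a candidate explanation of this overlap. If such signal arose with every antibody, K27me3 domains would be predicted to overlap K27ac too. Of these domains 24.1% did, against 41.3% in the lowest of 1000 shifted sets, or 43.8% against 44.7% with a 1 kb distance. Both marks sit on the same lysine of histone H3, so a low overlap can arise with or without such signal. This comparison therefore cannot decide the question. Signal from the PC and PH antibodies alone cannot be told apart from PRC1 binding, since 80.8% of PC regions outside domains also overlapped PH, which either would give. Of eye PH regions outside domains, 89.0% were also found in the wing disc, against 87.0% inside (Fisher exact adjusted p = 0.111). A role of PRC1 at active genes stays a hypothesis.

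A mutated chromosome may differ from its control in linked variants, in which case genes near the mutated one would be called more often. Among the 250 annotated genes on each side, the odds ratio of being called was 1.65 in Ez731, 1.23 in Su(z)12, 1.14 in ph505 and 1.36 in Psc-Su(z)2 (exact adjusted p = 0.0673, 0.379, 0.379 and 0.379). None passed, nor did any with all annotated genes as background (smallest exact adjusted p = 0.092), and linked differences of that size cannot be told apart from chance.

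Regions seen in the wing disc alone were narrower than those shared with the eye disc, with median widths of 1496 and 2106 bp for PC and 1333 and 1745 bp for PH (permutation p = 0.0001 each, the smallest possible). The same held for regions seen in the eye disc alone, at 1018 and 1256 bp for PC and 1030 and 1275 bp for PH (permutation p = 0.0001 each). For K27me3 the medians were 1201 and 17826 bp in the eye and 1151 and 20451 bp in the wing (permutation p = 0.0025 and 0.0001). A wider region is by itself more likely to overlap a region of the other list by 1 bp. The permutations did not take this into account, so these p-values in part restate the overlap rule. Of the 552 eye PC regions at least as wide as the median wing PC region, 63 (11.4%) had no wing PC region. Wing regions at least as wide as the median eye region were also missing from the eye disc, 1545 of 2706 for PC (57.1%) and 1283 of 3294 for PH (38.9%). Regions seen in the wing disc alone were thus not all narrower than the median eye region. That cut kept most of the 3716 wing PC and 5062 wing PH regions, whose median widths were 1684 and 1551 bp, against 1193 and 1249 bp in the eye. Depth and thresholds of the lists are unknown, so this cannot decide how far width accounts for these regions. For K27me3, 20 of the 316 regions seen in the wing disc alone were at least as wide as the median eye domain (6.33%).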
